A study of Mus musculus with 6 samples.

How the data were processed

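RNA of adrenal glands from 2 mouse strains, hypertensive BPH and hypotensive BPL, was hybridised to Affymetrix MG_U74Av2 arrays, with 3 arrays per strain. Each array carries 12488 probe sets, groups of short oligonucleotides that each query 1 transcript. The deposited values are intensities on a linear scale, 1 per probe set and array, with no detection call and no probe-level signal. The software that made them is not given in the sources used here. The mean after trimming 2% of probe sets at each end lay between 2501.3 and 2501.5 on all 6 arrays, so the authors' values had been scaled to a common level before they were deposited. The array run files that accompany the values name the chip type, chip lot, fluidics station and scan order, and hold no measurement.

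Because the trimmed means were equal, no further scaling was applied. Values under the 20th percentile of the whole table, an intensity of 201.3, were set to that floor and all values were then taken to log2. The floor understates the change of genes with low signal. Between 18.6% and 22.4% of all probe sets per array lay below it, but at most 0.14% of the tested ones. The 66 Affymetrix control probe sets were left out, as were probe sets whose mean over the 6 arrays lay under the 40th percentile, an intensity of 668.1. This left 7293 probe sets. Differences are BPH minus BPL on the log2 scale, fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. All tests are two-sided, and a probe set or gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values given for single genes are from limma. Means and SDs are of the intensities of the 3 arrays of a strain as deposited, without the floor. The number of arrays limits the precision.

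Gene names came from the platform's annotation, with 1 gene for 10855 probe sets, several for 396 and none for 1237. Of the 10855, 10839 were matched by gene number to a RefSeq table of the GRCm38.p6 assembly, from which the current symbol was taken. That table was used only for names and for which genes neighbour each other, and no coordinates are given, because no genome build is named with the values. Probe sets with several genes or none were not named. A gene was represented by its brightest tested probe set, which gave 5555 genes.

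Gene lists were tested with camera at a preset correlation between genes of 0.01, which asks whether the genes of a list lie higher or lower than the other tested genes. Of 32 lists, 30 had at least 5 tested members and were tested, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. The lists cover catecholamine synthesis, chromaffin granules, chromaffin and neuronal identity, steroid synthesis, zones of the adrenal cortex, cholesterol supply, the renin-angiotensin and other vasoactive systems, adrenergic receptors and G protein signalling, and ion transport. Further lists cover oxidative phosphorylation, the citric acid cycle with glycolysis and fat oxidation, antioxidant and glutathione enzymes, heat shock proteins, immediate-early and stress genes, the circadian clock, ribosomal proteins, the proteasome, the cell cycle, antigen presentation, the interferon response, complement, and sex-linked genes. The remaining lists hold markers of macrophages, lymphocytes, endothelium, fat, fibroblasts and capsule, smooth muscle, blood, kidney, Schwann cells and skeletal muscle. Some lists share members. Hsd3b6 and Mc2r are in the steroid and the cortex zone lists, and Cox7a1 and Cox8b in the fat and the oxidative phosphorylation lists. Orm1 is in the fat and complement lists, and Per1 and Per2 are in the immediate-early and clock lists. Other shared members include Dnajc5 (granule and heat shock), Ramp2 (vasoactive and endothelial), Rgs5 (G protein and smooth muscle) and C1qb (macrophage and complement). The oxidative phosphorylation list was built by name pattern and also took in assembly factors and the muscle isoform Cox6a2.

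The groups, the design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The named genes are the 12 called genes with the largest difference in each direction whose arrays did not overlap between strains, up to 4 members with the smallest p of each list described, and a fixed set of adrenal genes. Of that set, Dbh, Cyp11b1, Cyp11b2, Ren1, Agtr1a and Agtr1b were not analysed here. Alternatives set beforehand were quantile normalization, scaling to one median, a floor at the 10th percentile, an added offset in place of the floor, no filter, a filter at the 60th percentile, eBayes without the trend or with robust estimation, the replicate number as a block, the fluidics station as a block, the mean of a gene's probe sets, an adjusted p under 0.01, a fold of at least 1.5, and leaving out each array in turn. The fit within fluidics station 1 was chosen after the data were seen. So was the fit without the 2 arrays with the most skeletal muscle transcripts, BPH 1 and BPL 2. So was the mean log2 value of skeletal muscle or brown fat markers as a covariate. The brown fat markers (Ucp1, Cidea, Cox7a1, Cox8b) and the general fat markers (Adipoq, Car3, Cidec, Fabp4, Lep, Retn) were split from the fat list after its values were seen. The brown fat marker mean did not overlap between the strains. As a covariate it therefore follows strain, and list values from that fit cannot separate the 2. Within each strain the brown fat marker mean was highest on a muscle-bearing array, 13.71 on BPH 1 and 15.95 on BPL 2. The fit without these arrays therefore also leaves out the most brown fat transcript, and its shifts cannot be laid to muscle alone.

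All arrays shared 1 chip lot and 1 scan day. The 3 BPL arrays were scanned before the 3 BPH arrays, so scan order and strain cannot be told apart. BPH 1 and BPH 2 were processed on fluidics station 2, and BPH 3 and the BPL arrays on station 1. Values with the station as a block therefore rest on BPH 3 against the BPL arrays, as do those within station 1. These 2 fits are 1 comparison with 1 BPH array, so a call kept or gained in them is not read as support. Station 2 held no BPL array and gives no value of its own. The labels number the replicates but do not say whether they are separate animals, so the p-values measure the spread between these samples, which may be technical. Sex and age of the mice are not stated in the labels.

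The procedure was tested on simulated data with the means and spread of these arrays, in 10 runs with 200 changed probe sets each. It recovered 19.4% of probe sets changed 1.5-fold, 68.8% of those changed 2-fold and 88.5% of those changed 4-fold, and 5.1% of the called probe sets were false. Of random lists, 4.0% passed an unadjusted p under 0.05 in camera. The simulated probe sets varied independently of each other, so this does not test lists whose genes move together. In the real data the estimated correlation of the lists that passed ran from 0.196 for immediate-early genes to 0.777 for fat. It was 0.593 for oxidative phosphorylation, far above the preset 0.01.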

Results

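The data describe whole adrenal glands of mice from BPH and BPL, inbred strains bred for high and for low blood pressure. The adrenal gland joins a cortex that makes steroid hormones with a medulla whose chromaffin cells make catecholamines. The comparison asks which adrenal transcripts differ between the hypertensive and the hypotensive strain. There were 3 arrays per strain, and the median intensity per array lay between 1003.5 and 1114.7. Across the 7293 tested probe sets, which are not independent replicates, log2 intensities of 2 arrays of the same strain correlated with r between 0.924 and 0.962. For 2 arrays of different strains r lay between 0.894 and 0.938.

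Of 7293 probe sets tested, 184 passed the threshold, 114 higher and 70 lower in BPH, and of 5555 genes 138 passed it, 87 higher and 51 lower. The 3 BPH arrays lay wholly above or below the 3 BPL arrays for all 138. Chance gives that separation for 10% of unselected genes, but a small p on these same arrays nearly ensures it, so it adds no support. A difference of at least 2-fold was found for 79 genes. The largest difference was in Capg, an actin filament capping protein, with an intensity of 3668 ± 113 (SD, n = 3) in BPH and 194.3 ± 119.2 (SD, n = 3) in BPL. The log2 difference was 3.96 (SE 0.27, adjusted p = 0.000247), and since 2 of the BPL arrays lay at the floor it understates the difference at this probe set. Another Capg probe set, with a mean log2 intensity of 9.54 against 9.86, did not follow. Its log2 difference was -0.42, so which of the 2 reflects the Capg transcript stays open. Other probe sets of Gadd45b (2.54) and Ucp1 (-2.14) did follow. H2-Ea, a class II antigen-presenting chain, was 3.27 higher on the log2 scale (SE 0.28, adjusted p = 0.000934), with 1 BPL array at the floor. The chemokine receptor gene Cxcr4 rose from 791.8 ± 276.8 in BPL to 5611 ± 782.7 in BPH (SD, n = 3), a log2 difference of 2.88 (SE 0.26). The other 9 of the 12 largest increases ran from 3.00 for Gadd45b to 1.74 for Aldh1a1. Among them, Aldh1a7 at 2.82 and Aldh1a1 are near-identical aldehyde dehydrogenases whose probes can detect each other. Mgst2 (2.11) is a microsomal glutathione transferase, and Amacr (2.29) acts in peroxisomal fat oxidation. Aldh1a7 and Amacr each had 1 BPL array at the floor, so their values understate the change. Gdpd3 (2.61), Nr4a1 (2.36), Itih2 (2.22) and Thumpd1 (2.06) complete the group.

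In the other direction, H2-Q10, a class I histocompatibility gene, had an intensity of 1020 ± 85.6 in BPH and 10670 ± 6158 in BPL (SD, n = 3), a log2 difference of -3.24 (SE 0.33, adjusted p = 0.00233). Ucp1, the uncoupling protein of brown fat, followed at -2.69 (SE 0.41, adjusted p = 0.013), with 9169 ± 3991 in BPH and 60880 ± 33500 in BPL (SD, n = 3). Fasn, the fatty acid synthase, differed by -2.16 (SE 0.28), and the bicarbonate transporter gene Slc4a4 by -2.07 (SE 0.39). The glycerol phosphate dehydrogenases Gpd2 (-1.94) and Gpd1 (-1.91), the aldehyde dehydrogenase Aldh9a1 (-1.87), the glutathione transferase Mgst1 (-1.80) and the uncoupling protein Ucp3 (-1.71) were lower as well. Spg21 (-1.96), the apolipoprotein gene Apoc1 (-1.71) and the acute phase gene Orm1 (-1.69) make up the rest of the 12. All of the 12 but Spg21 and Mgst1 were highest on BPL 2, the array with the highest mean of brown fat markers. Whether their differences arise in adrenal cells or in adherent tissue was not settled.

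**Figure D1:**
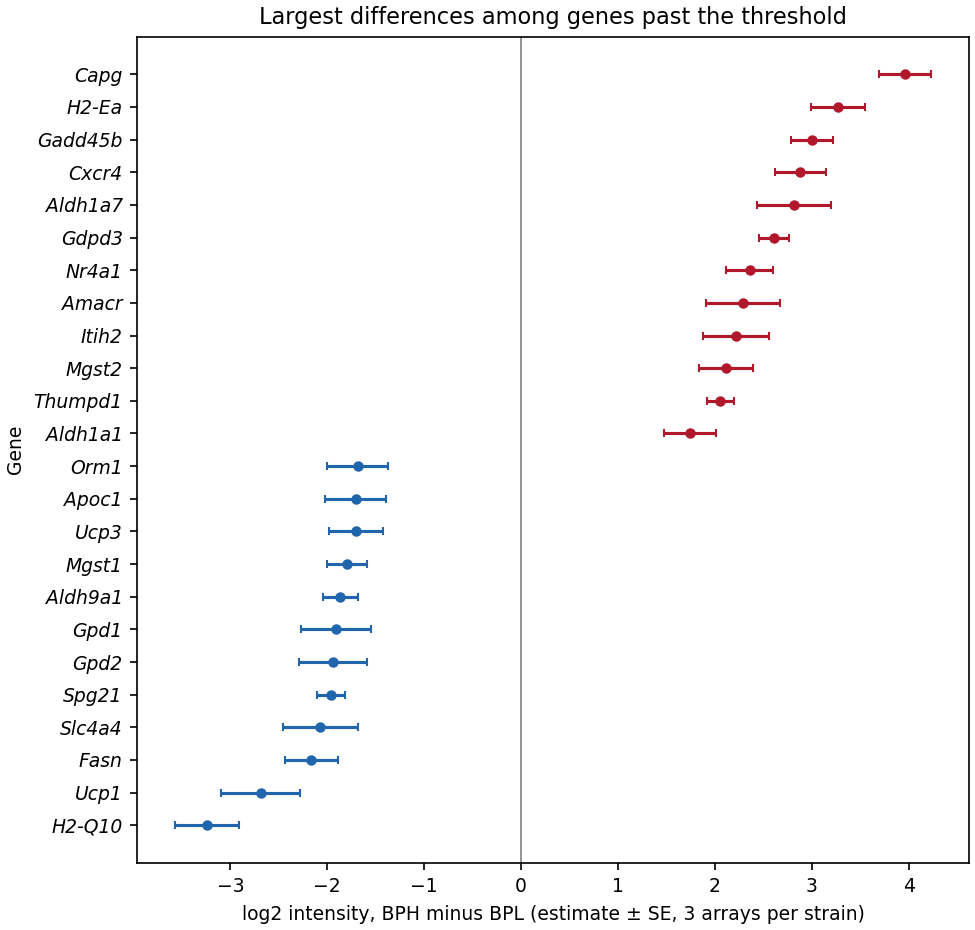
Log2 difference in intensity, BPH minus BPL (horizontal axis), of the 12 genes with the largest difference in each direction among genes past the threshold (vertical axis); points are limma estimates and bars are SEs, from 3 arrays per strain. The differences run from -3.24 for H2-Q10 to 3.96 for Capg.

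With the fluidics station as a block 12 genes passed, 10 of them among the 138, and within station 1 alone 7 passed, 4 of them among the 138. The log2 difference within station 1 was 3.94 for Capg, 3.15 for Gadd45b, 2.59 for Nr4a1, 1.28 for Rgs2, -3.27 for H2-Q10 and -2.63 for Ucp1, and the block gave the same values. The count depended on single arrays: it was 68 without BPH 1, 32 without BPH 2, 33 without BPH 3, 60 without BPL 1 and 298 without BPL 3. It was 48 with no filter on low values, 65 without the intensity trend and 129 without the 2 arrays that carried skeletal muscle transcripts. Of 30 gene lists 6 passed in camera at the preset correlation and 9 with the station as a block or within station 1. With an estimated correlation 0 passed, with 0 at an unadjusted p under 0.05, and by fry 0, with 2.

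Catecholamine genes did not pass the test as a group, though several stood higher in BPH. None of the 10 tested members was called over all genes in limma, with 5 at an unadjusted p under 0.05, and 4 higher and 1 lower passed when adjusted over the list alone. Pnmt, which converts noradrenaline to adrenaline, had an intensity of 36340 ± 5461 in BPH and 19090 ± 6431 in BPL (SD, n = 3), a log2 difference of 0.98 (SE 0.24, adjusted p = 0.0723). Th, the rate-limiting enzyme of catecholamine synthesis, differed by 0.78 (SE 0.28, adjusted p = 0.168). Gch1 and Qdpr, which make and recycle its cofactor tetrahydrobiopterin, differed by 0.77 and 0.41, and Pts, of the same cofactor pathway, by -0.45. Ddc, the next enzyme of the pathway, differed by 0.08 (SE 0.46). The median of the list was 0.14 (camera adjusted p = 0.359), 0.26 with the station as a block and within station 1, and -0.02 without the 2 arrays with skeletal muscle transcripts (adjusted p = 0.854).

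Chromaffin granule genes did not pass the test as a group either, with a positive difference for 20 of 23 and 1 called. Penk, which encodes enkephalin precursor, was 0.61 higher (SE 0.13, adjusted p = 0.0476), and 2 members passed when adjusted over the list alone. The granule proteins secretogranin II (Scg2, 1.19, SE 0.28, adjusted p = 0.0686) and chromogranin A (Chga, 0.69, SE 0.27, adjusted p = 0.206) were not called over all genes, nor were neuropeptide Y (Npy, 0.69, SE 0.44, adjusted p = 0.419), galanin (Gal, 0.55) and Vamp2 (0.50). The list median was 0.23 (camera adjusted p = 0.129). With the station as a block and within station 1, both BPH 3 alone against the BPL arrays, it was 0.33. Over the alternatives the adjusted p ran from 0.000975 to 0.814. The median was 0.14 without the 2 arrays with skeletal muscle transcripts (adjusted p = 0.421) and -0.25 with the brown fat marker mean as a covariate (adjusted p = 0.167). The array BPL 3 stood above BPL 1 and BPL 2 in several of these genes, but not in the called Penk (5899, 5444 and 5438 on BPL 1, 2 and 3). The Th intensity of BPL 3 was 22493, against 12618 on BPL 1 and 9236 on BPL 2, while the BPH arrays had 25099, 21439 and 24862. Without BPL 3 the median was 0.49 for granule genes (adjusted p = 0.000975) and 0.34 for catecholamine genes (adjusted p = 0.0465, in a range from 0.0465 to 0.854). Chromaffin and neuronal identity genes had a median of 0.00 over 15 members and a mean of -0.02 (camera adjusted p = 0.725). None was called and none had an unadjusted p under 0.05 in limma. Gata2 (0.28), Uchl1 (0.36), Stmn3 (-0.45) and Stmn2 (-0.37) had the smallest p-values.

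**Figure D2:**
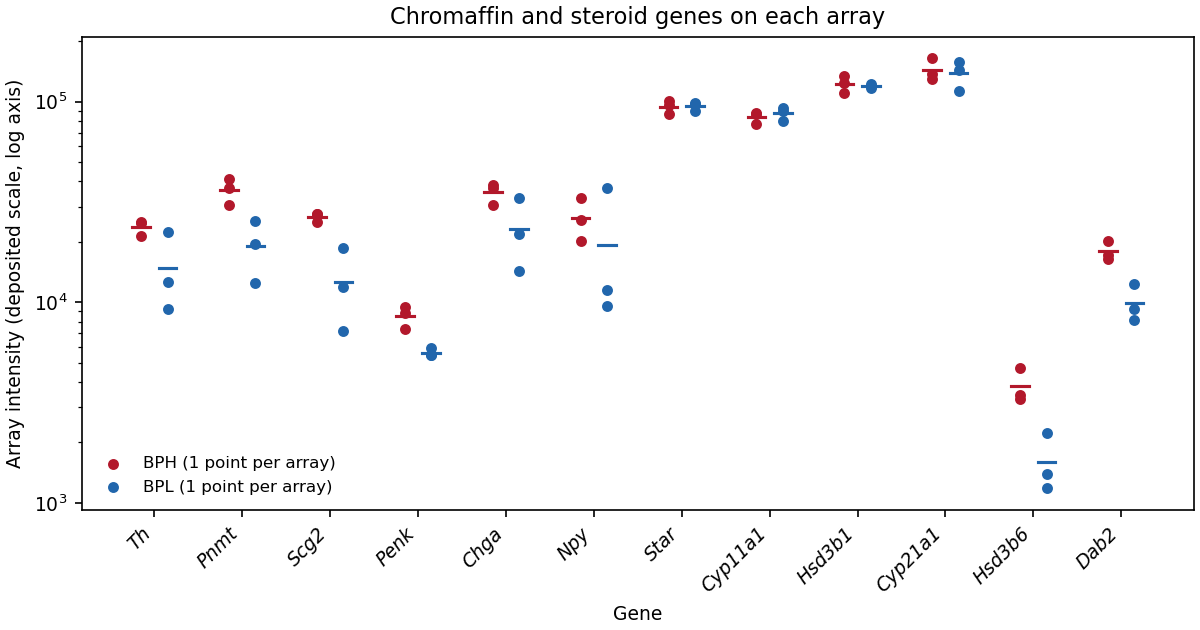
Intensity per array (vertical axis), on a log axis, of 12 chromaffin and steroid genes named by the rule (horizontal axis); points are the 3 BPH and 3 BPL arrays and lines are strain means. Pnmt lies at 30494 or above on the BPH arrays and at 25316 or below on the BPL arrays, and Star, Cyp11a1, Hsd3b1 and Cyp21a1 overlap between strains.

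The core enzymes of steroid synthesis overlapped between the strains. Star, which carries cholesterol into mitochondria, had an intensity of 94390 ± 7023 in BPH and 95130 ± 4755 in BPL (SD, n = 3). The log2 differences were -0.01 for Star (SE 0.14), -0.06 for Cyp11a1, the side chain cleavage enzyme (SE 0.14), 0.03 for Hsd3b1 (SE 0.15) and 0.06 for Cyp21a1 (SE 0.18). Of 18 tested members of the list, 1 was called, and 2 higher and 1 lower passed when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.406; 0.04 with the station as a block and within station 1). The called gene was Hsd3b6, a 3-beta-hydroxysteroid dehydrogenase whose near-identical copy Hsd3b1 can cross-hybridise. It was 1.29 higher in BPH (SE 0.25, adjusted p = 0.0344). Cyb5a, a cofactor of steroid enzymes (0.49, adjusted p = 0.0609), Hsd17b4 (-0.79, adjusted p = 0.0755) and the nuclear receptor gene Nr0b1 (0.60, adjusted p = 0.247) were not called.

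Genes that mark zones of the cortex were higher in BPH as a group. Of 12 members 11 had a positive difference, with a median of 0.69 (camera adjusted p = 0.00393), and the list did not pass with an estimated correlation (adjusted p = 0.754) or by fry (adjusted p = 0.212). Dab2, a marker of the outer zone, was 0.88 higher (SE 0.17, adjusted p = 0.0344), and Hsd3b6 was the other called member. Wnt4 (0.88, adjusted p = 0.0795), a signal of the outer cortex, passed when adjusted over the list alone, in which 3 members passed, and Dlk1 (0.85, adjusted p = 0.201) did not. The median was 0.70 with the station as a block and within station 1, both BPH 3 alone against the BPL arrays. It was 0.30 without BPL 2 (adjusted p = 0.0382). The call ended without the filter on low values (0.32, adjusted p = 0.083) and without the 2 arrays with skeletal muscle transcripts (0.36, adjusted p = 0.0607), and over the alternatives the adjusted p ran from 0.000713 to 0.754. The brown fat marker mean was lower in BPH by 1.76 on the log2 scale, as set out for the fat markers, and with it as a covariate the median was -0.05. Since that covariate follows strain, this value decides nothing.

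Cholesterol supply genes had a median of -0.17 over 28 members and were not called as a list (camera adjusted p = 0.0807). The median was 0.00 with the station as a block and within station 1, and without BPH 2 or BPH 3 the list passed at -0.17 and -0.21. The hormone-sensitive lipase gene Lipe, whose product frees stored cholesterol and fat and is abundant in adipocytes, had a log2 difference of -1.25 (SE 0.25, adjusted p = 0.0375). It was the 1 called member, and 1 higher and 4 lower passed when adjusted over the list alone. Dhcr7 (0.69, adjusted p = 0.0656) and Fdps (-0.62, adjusted p = 0.0779), both enzymes of sterol synthesis, and the lipid carrier Scp2 (-0.58, adjusted p = 0.0991) were not called.

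Immediate-early and stress genes were higher in BPH. Of 36 tested members 13 were called, all higher, and when adjusted over the list alone 15 passed higher and 1 lower. Gadd45b, a stress-induced growth arrest gene, had an intensity of 25440 ± 2982 in BPH and 3276 ± 955.4 in BPL (SD, n = 3), a log2 difference of 3.00 (SE 0.22, adjusted p = 0.000297). Nr4a1, an orphan receptor induced by corticotropin in the cortex, had 47370 ± 9878 and 9406 ± 3045 (SD, n = 3), a log2 difference of 2.36 (SE 0.24, adjusted p = 0.00233). Junb (1.34, SE 0.17, adjusted p = 0.00606) and Per1 (1.30, SE 0.18, adjusted p = 0.008), a clock gene that is also induced acutely, rose too. The list median was 0.48 (camera adjusted p = 5.02e-05), but the list did not pass with an estimated correlation (adjusted p = 0.754) or by fry (adjusted p = 0.212). When 1 array was left out the camera adjusted p ran from 3.35e-07 to 0.00168. With the station as a block and within station 1, both BPH 3 alone against the BPL arrays, the median was 0.78. BPH 3 had the highest mean of these genes, 12.291, against 11.866 on BPH 1 and 12.06 on BPH 2. With the brown fat marker mean as a covariate, which follows strain, the median was 0.22 (adjusted p = 0.00391).

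Clock genes as a list did not pass (13 members, median 0.02, camera adjusted p = 0.979; 0.05 with the station as a block and within station 1). Per1 was called, and Per1 and Per2 (1.02, adjusted p = 0.0977) passed when adjusted over the list alone, while Nr1d2 (0.29) and Nr1d1 (-0.39) did not. Heat shock proteins and chaperones had a median of 0.12 over 60 members (camera adjusted p = 0.171; 0.14 with the station as a block and within station 1). The co-chaperone Bag3 was the 1 called member over all genes and over the list alone (0.92, SE 0.14, adjusted p = 0.0124), and Dnajb2 (0.53), Hspb11 (0.90) and Dnajc15 (-0.48) were not called.

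Interferon response genes were lower in BPH at the edge of the threshold. Of 18 tested members 12 had a negative difference, with a median of -0.24 (camera adjusted p = 0.0442; adjusted p = 0.754 with an estimated correlation and 0.319 by fry, in a range over the alternatives from 0.000295 to 0.754). Ifit3 (-1.01, SE 0.22, adjusted p = 0.0476) and Ifi27 (-0.55, SE 0.12, adjusted p = 0.0488), both induced by interferon, were called, and 3 members passed lower when adjusted over the list alone. Gbp3 (-0.62, adjusted p = 0.0599) and Rsad2 (-0.70, adjusted p = 0.166) were not called. With the station as a block and within station 1, both BPH 3 alone against the BPL arrays, the median was -0.30. The list lost its call without the 2 arrays with skeletal muscle transcripts (-0.25), and without BPH 1 (-0.16), BPH 3 (-0.19) or BPL 3 (-0.15). The call was also lost under quantile normalization (-0.23), with the offset (-0.21), the replicate block (-0.24) or the muscle covariate (-0.22), and without the filter (-0.24). With the brown fat marker mean as a covariate the median was -0.51 (adjusted p = 0.000295). Antigen presentation genes were not called as a list (29 members, median 0.24, camera adjusted p = 0.202; 0.10 with the station as a block and within station 1). H2-Ea was called higher and H2-Q10 lower, over all genes and over the list alone, and Tap2 (0.56) was not called. H2-D1 was not called at its brightest probe set (0.42), but another of its probe sets was called at 1.92. Histocompatibility genes vary in sequence between strains, and probes for 1 can detect another.

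Genes of mitochondrial energy production were lower in BPH as a group. Of 66 oxidative phosphorylation genes, 64 had a negative difference, with a median of -0.48 (camera adjusted p = 1.36e-15). The list did not pass with an estimated correlation (adjusted p = 0.754) or by fry (adjusted p = 0.212), and over the alternatives the adjusted p ran from 2.79e-20 to 0.754. Over all genes 2 were called, Ndufa7 of complex I (-0.68, SE 0.13, adjusted p = 0.034) and Sdhd of complex II (-1.19, SE 0.23, adjusted p = 0.0375), and 13 passed lower when adjusted over the list alone. Cox8b (-1.47, adjusted p = 0.0552) and Cox6b2 (-1.35, adjusted p = 0.064) were not called over all genes. The median was -0.49 with the station as a block and within station 1, -0.37 without the 2 arrays with skeletal muscle transcripts and -0.28 without BPL 2. The mean of the brown fat markers was lower in BPH too (-1.76, SE 0.54), and with it as a covariate the median turned to 0.19 (adjusted p = 0.00695). That covariate follows strain and includes Cox7a1 and Cox8b of this list, so the turn decides nothing.

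Genes of the citric acid cycle, glycolysis and fat oxidation had a median of -0.45 over 54 members (camera adjusted p = 6.9e-10), again not passing with an estimated correlation (adjusted p = 0.754) or by fry (adjusted p = 0.212), in a range over the alternatives from 2.73e-12 to 0.754. Of the 5 called members, all lower in BPH, Fasn and the transketolase Tkt (-1.58, SE 0.24, adjusted p = 0.0121) act in fatty acid synthesis and the pentose phosphate path. Hexokinase 2 (Hk2, -1.59, SE 0.31, adjusted p = 0.0375) acts in glycolysis and Idh3a (-0.93, SE 0.18, adjusted p = 0.0375) in the citric acid cycle. The fifth, Pdha1 of pyruvate dehydrogenase (-1.11), was chosen after its values were seen. When adjusted over the list alone, 1 passed higher and 21 lower. The median was -0.43 with the station as a block and within station 1, -0.29 without the 2 arrays with skeletal muscle transcripts and -0.24 without BPL 2. With the brown fat marker mean as a covariate it turned to 0.09 (adjusted p = 0.108). That covariate follows strain, so the turn decides nothing.

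Fat markers were lower in BPH as a group. The fat list had a median of -0.62 over 14 members (camera adjusted p = 0.00115), and did not pass with an estimated correlation (adjusted p = 0.754) or by fry (adjusted p = 0.32), in a range over the alternatives from 5.25e-05 to 0.754. Ucp1 and Orm1 were called, and 2 higher and 7 lower passed when adjusted over the list alone. Cox8b and Cox7a1 (-1.65, adjusted p = 0.0724), subunits abundant in brown fat, were not called over all genes. The mean log2 intensity of 4 brown fat markers was 13.71, 12.84 and 13.32 on BPH 1, 2 and 3, and 14.85, 15.95 and 14.35 on BPL 1, 2 and 3. The strain difference was -1.76 (SE 0.54; exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). For 6 general fat markers, split from the list after its values were seen, it was -0.02 (SE 0.22; exact permutation p = 1.0). The fat list median was -0.57 with the station as a block and within station 1, -0.36 without the 2 arrays with skeletal muscle transcripts and -0.29 without BPL 2. With the brown fat marker mean as a covariate no gene passed in limma, with 407 at an unadjusted p under 0.05. The fat list median then turned to 0.35 (adjusted p = 0.00611). The 4 markers are members of this list and their mean follows strain, so this turn is partly built in and decides nothing.

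**Figure D3:**
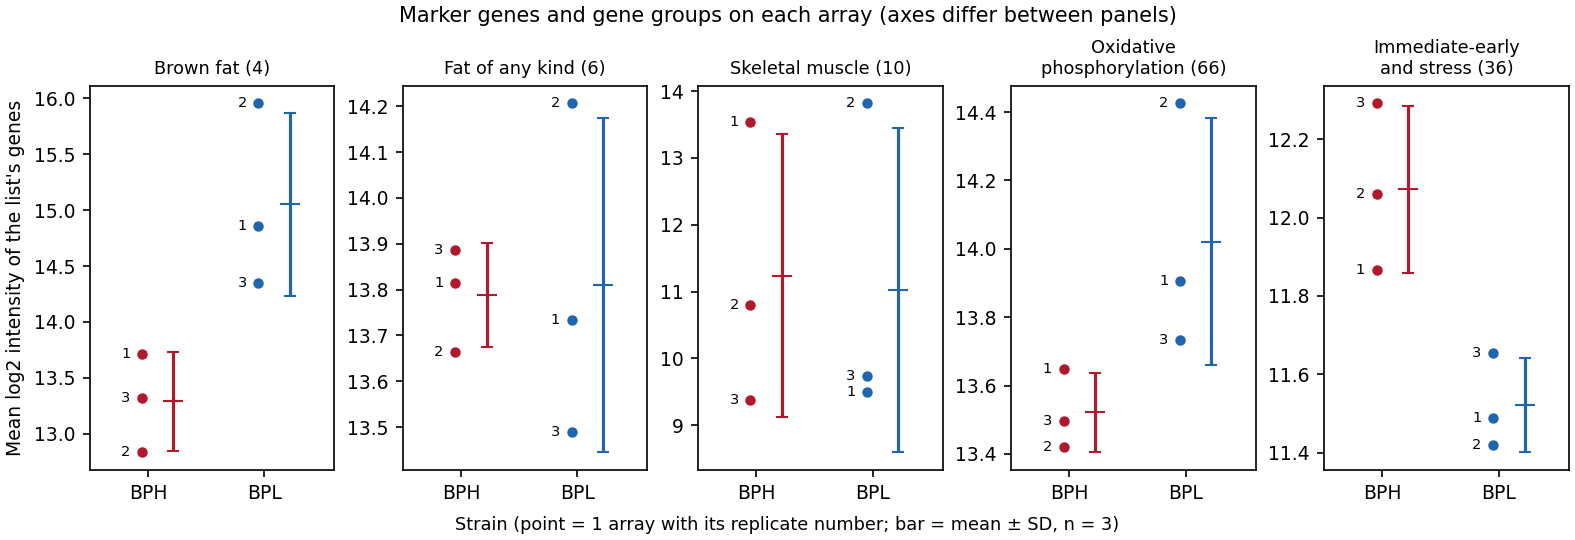
Mean log2 intensity per array (vertical axes) of brown fat, general fat, skeletal muscle, oxidative phosphorylation and immediate-early genes on the 3 BPH and 3 BPL arrays (horizontal axes); points are arrays with their replicate number and bars are means ± SD. Brown fat markers lie between 12.84 and 13.71 on the BPH arrays and between 14.35 and 15.95 on the BPL arrays.

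Skeletal muscle transcripts were strongest on 1 array of each strain. Their mean log2 intensity was 13.54 on BPH 1 and 13.81 on BPL 2, 10.80 on BPH 2, and between 9.37 and 9.74 on the other arrays. The skeletal actin gene Acta1 had an intensity of 41852 on BPH 1, 62862 on BPL 2 and 5529 on BPH 2. It had 1549 on BPH 3, 321 on BPL 1 and 1833 on BPL 3. The fits without BPH 1 and BPL 2 therefore still hold some muscle transcript on BPH 2, with Acta1 1.93 higher in BPH. Those fits also leave out the array with the highest brown fat marker mean of each strain. Of the 10 tested muscle genes none was called and none had an unadjusted p under 0.05 in limma. The median difference was 0.26 while the test pointed lower (camera adjusted p = 0.979), and the differences of Myh4 (1.34, SE 1.85), Acta1 (1.09, SE 1.76), Tnnt3 (0.61, SE 1.62) and Myh1 (-1.60, SE 1.43) were smaller than their errors or close to them. With the station as a block and within station 1, which leave the muscle-bearing BPL 2 but not BPH 1 in the comparison, the median was -1.52.

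Few of the tested genes of blood pressure control were called. Of 54 vasoactive genes listed, 38 were on the array and 20 were tested, without Ren1, Agtr1a and Agtr1b. Adra2c was the only adrenergic receptor gene tested. In the simulation 19.4% of 1.5-fold changes were recovered, so few calls do not mean few differences. None of the 20 tested genes of the renin-angiotensin and other vasoactive systems was called in limma over all genes or over the list alone, with 2 at an unadjusted p under 0.05. The median was 0.08 and the mean -0.01, with the test pointing lower (camera adjusted p = 0.933; 0.15 with the station as a block and within station 1). The kininogen gene Kng1 differed by -1.07 (SE 0.35, adjusted p = 0.145), Ramp2 by -0.34, Ramp3 by -0.39 and the kinase gene Sgk1 by 0.27. Among 25 genes of adrenergic receptors and G protein signalling, Rgs2, a brake on signalling through Gq-coupled receptors, was 1.30 higher in BPH (SE 0.15, adjusted p = 0.00437), with intensities of 29950 ± 3218 and 12200 ± 2025 (SD, n = 3). It was the 1 called member, and 2 passed when adjusted over the list alone. Gnb1 (0.46), Gnao1 (-0.38) and Prkaca (-0.37) were not called over all genes. The list median was 0.03, with the test pointing lower (camera adjusted p = 0.979; 0.12 with the station as a block and within station 1). Of 17 ion transport genes none was called in limma, with 4 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone. The potassium channel genes Kcnk2 (0.99, SE 0.24, adjusted p = 0.0686) and Kcnk1 (0.77, adjusted p = 0.142), Slc4a3 (0.50) and Atp1b3 (0.34) had the smallest p-values. The list median was 0.17 (camera adjusted p = 0.171; 0.21 with the station as a block and within station 1).

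**Figure D4:**
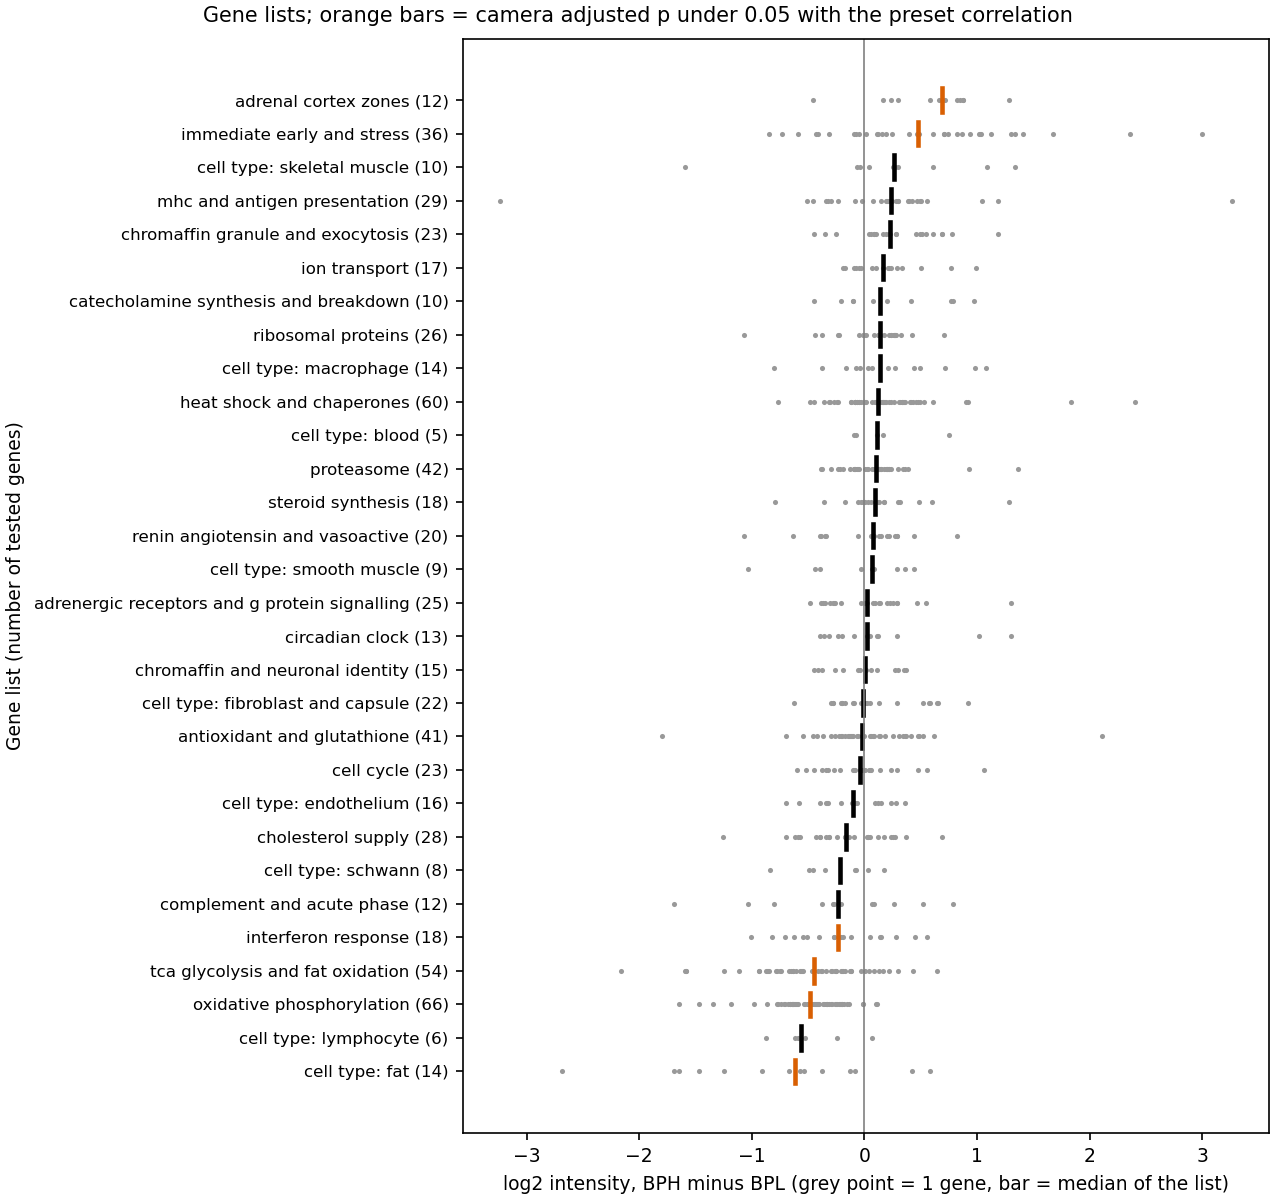
Median log2 difference, BPH minus BPL (horizontal axis), of each of the 30 tested gene lists (vertical axis), as bars over grey points for single genes, with lists past the camera threshold at the preset correlation in orange. The called lists range from -0.62 for fat markers to 0.69 for cortex zone genes.

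Apart from fat, no list of other cell types passed at the preset correlation, and lymphocyte markers came closest. Macrophage markers had a median of 0.14 over 14 members (camera adjusted p = 0.359; 0.10 with the station as a block and within station 1). None was called, 7 had an unadjusted p under 0.05 in limma, and 2 higher and 1 lower passed when adjusted over the list alone. Lyz2 differed by 0.50, Lgals3 by 1.08, Csf1r by 0.44 and C1qb by -0.80. Lymphocyte markers had a median of -0.56 over 6 members (camera adjusted p = 0.0522), with Ighm at -0.53, Coro1a at -0.87, Cd79a at -0.59 and Cd4 at -0.62. None was called over all genes or over the list alone, and 1 had an unadjusted p under 0.05 in limma. That list passed without BPH 2 (-0.47), BPH 3 (-0.43) or BPL 2 (-0.71). Its median was -0.34 with the station as a block and within station 1. Endothelial markers had a median of -0.10 over 16 members (camera adjusted p = 0.326; -0.14 with the station as a block and within station 1), with Tie1 at -0.70, Tek at 0.36, Ramp2 at -0.34 and Flt4 at 0.28. None was called over all genes or over the list alone, and 3 had an unadjusted p under 0.05 in limma.

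Fibroblast and capsule markers had a median of -0.01 and a mean of 0.09 over 22 members, with the test pointing higher (camera adjusted p = 0.849; 0.09 with the station as a block and within station 1). None was called over all genes and 7 had an unadjusted p under 0.05 in limma, while 6 higher and 1 lower passed when adjusted over the list alone, among them Dcn (0.52), Gsn (0.65), Mgp (0.58) and Bgn (0.58). Smooth muscle markers had a median of 0.07 and a mean of -0.07 over 9 members, with the test pointing lower (camera adjusted p = 0.979; 0.18 with the station as a block and within station 1). None was called over all genes, 3 had an unadjusted p under 0.05 in limma, and 1 higher and 1 lower passed when adjusted over the list alone. Myh11 differed by -1.04, Tagln by 0.44, Actg2 by 0.36 and Rgs5 by 0.29. Blood markers had a median of 0.11 over 5 members (camera adjusted p = 0.526; 0.15 with the station as a block and within station 1). The carbonic anhydrase gene Car2 was 0.75 higher (SE 0.16, adjusted p = 0.0458) and the 1 called member over all genes and over the list alone, and Hbb-b2 (0.17), Ank1 (0.11) and Hba-a1 (-0.09) were not called. Schwann cell markers had a median of -0.22 over 8 members (camera adjusted p = 0.135; -0.11 with the station as a block and within station 1). None was called over all genes or over the list alone, and 2 had an unadjusted p under 0.05 in limma. Pmp22 differed by -0.49, Sox10 by -0.35, Gfap by -0.84 and Mag by -0.46. Only 3 kidney markers were tested, too few for a list test. Cyp2e1, a cytochrome P450 gene that the liver expresses strongly too, was 1.48 higher in BPH (SE 0.16, adjusted p = 0.00233), with Cyp4b1 at 0.37 and Aqp1 at -0.79. When adjusted over that list alone, 2 passed higher and 1 lower.

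The labels do not state the sex of the mice. The Y-linked gene Eif2s3y had intensities of 1988, 2654 and 2429 on BPH 1, 2 and 3 and of 1505, 1540 and 1360 on BPL 1, 2 and 3. Uty, also Y-linked, had 566, 1330 and 977 on the BPH arrays and 708, 660 and 689 on the BPL arrays. Xist, the transcript of the inactive X chromosome, lay below the filter at 414, 335 and 128 on the BPH arrays and 333, 163 and 44 on the BPL arrays. Kdm5d was also below the filter, between 66 and 236 on the BPH arrays and between 346 and 534 on the BPL arrays.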

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

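The fits within station 1, without the muscle-bearing arrays (BPH 1 and BPL 2) and with a marker mean as covariate were chosen after the data were seen. The strains did not overlap in any of the 138 called genes, which fixes their sign when arrays are left out. The filter at the 60th percentile tested 124 of them, and 1 changed sign when a gene was the mean of its probe sets. Over all alternatives the 142 named genes gave 2956 values, of which 289 lost and 63 gained a call. No value called in either fit changed sign, but 30 of these genes changed sign without a call, in 60 values. Called genes stayed within 1.5 times 138 under quantile normalization (149), scaling to one median (127), the lower floor (141), the offset (139), the stricter filter (162), robust estimation (147), the fold of at least 1.5 (135) and without the muscle-bearing arrays (129). Where the count moved further, genes and probe sets were 48 and 52 with no filter, where more genes were tested, 65 and 83 without the trend, 12 and 18 with the station as a block, 7 and 7 within station 1, where fewer arrays were compared, and 39 and 48 at an adjusted p under 0.01. With muscle as a covariate they were 264 and 318, and with brown fat 0 and 0 in limma, with 407 genes and 520 probe sets at an unadjusted p under 0.05. All 138 genes kept their sign in that last fit, with log2 differences a median 0.719 times and SEs 1.72 times those without the covariate, which follows strain. Leaving out 1 array gave 32 to 298 genes and 42 to 361 probe sets. The scalings moved the median difference of all genes between 0.005 and 0.037.

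Lists past the threshold numbered 4 to 9 under the other settings, 10 with brown fat as a covariate, 0 with an estimated correlation and 0 by fry, with 0 and 2 at an unadjusted p under 0.05. The last 2 tests leave the medians as they were: 0.69 for cortex zones, 0.48 for immediate-early genes, -0.24 for interferon, -0.62 for fat, -0.48 for oxidative phosphorylation and -0.45 for the citric acid cycle list. The cause of other lost or gained calls was not tested. When 1 array was left out, medians ranged from 0.30 to 0.85 for cortex zones, 0.33 to 0.70 for immediate-early genes, -0.79 to -0.29 for fat, -0.61 to -0.28 for oxidative phosphorylation and -0.56 to -0.24 for the citric acid cycle list, and these 5 kept their call; for all but immediate-early genes the value nearest 0 was that without BPL 2. Cortex zones lost their call without the filter (0.32) and without the muscle-bearing arrays (0.36). Interferon lost it with quantile normalization (-0.23), the offset (-0.21), no filter (-0.24), the muscle covariate (-0.22) and without the muscle-bearing arrays (-0.25), and ranged from -0.35 to -0.15 when 1 array was left out. With brown fat as a covariate, cortex zones (-0.047), fat (0.35), oxidative phosphorylation (0.19) and the citric acid cycle list (0.086) reversed. Skeletal muscle gained a call there as higher (4.93), where the test without the covariate, not called, had pointed lower beside a median of 0.26, and cell cycle (-0.51), complement (-0.33), blood (0.55), lymphocytes (-0.92) and Schwann cells (-0.50) gained a call. Lymphocytes also gained it with the offset (-0.50), the station as a block and within station 1 (-0.34), the muscle covariate (-0.54), the mean of probe sets (-0.60) and without the muscle-bearing arrays (-0.72), with -0.71 to -0.39 when 1 array was left out. Granule genes gained it with the stricter filter (0.48) and the station as a block and within station 1 (0.33), with 0.06 to 0.49 when 1 array was left out. Cholesterol supply gained it with the stricter filter (-0.17) and the mean of probe sets (-0.17), with -0.24 to -0.046 when 1 array was left out, catecholamine genes only without BPL 3, in a range of 0.00 to 0.34, and skeletal muscle with the station as a block and within station 1 (-1.52).

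Arrays with the same replicate number did not deviate together, with correlations across probe sets of -0.219, -0.084 and 0.012 for numbers 1, 2 and 3. With the replicate block 96 genes, 124 probe sets and 7 lists passed. Interferon (-0.24) lost its call there, and granule genes (0.23) and lymphocytes (-0.56) gained one. Low signal limits the rest: the floor of 201.3 understates the change of dim genes, and the 40th percentile filter leaves dim transcripts untested.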

Other observations

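Glutathione transferases of the microsomal family moved apart between the strains. Mgst1 was lower in BPH, with an intensity of 9196 ± 2081 against 32030 ± 7097 in BPL (SD, n = 3) and a log2 difference of -1.80 (SE 0.21, adjusted p = 0.00404), and Mgst2 (2.11, SE 0.28, adjusted p = 0.00651) and Mgst3 (0.62, SE 0.11, adjusted p = 0.0302) were higher. These 3 were the called members of 41 antioxidant and glutathione genes, of which 5 higher and 4 lower passed when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, differed by -0.70 (adjusted p = 0.0516). The list went both ways, with a median of -0.02, a mean of 0.01 and a test pointing lower (camera adjusted p = 0.97; 0.07 with the station as a block and within station 1).

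Single genes also stood out in lists that did not pass. The proteasome subunit gene Psmb6 was 1.36 higher in BPH (SE 0.14, adjusted p = 0.00233), while the 42 proteasome genes had a median of 0.10 (camera adjusted p = 0.359; 0.03 with the station as a block and within station 1) and 2 passed higher when adjusted over the list alone. Psmg2 differed by 0.93, Psmc6 by -0.37 and Psmb2 by -0.38. The ribosomal protein gene Rps7 was 0.70 higher (SE 0.13, adjusted p = 0.0283) and the 1 called member over all genes and over the list alone, among 26 with a median of 0.14 (camera adjusted p = 0.316; 0.06 with the station as a block and within station 1). Rps28 differed by -0.44, Rpsa by 0.32 and Rps3 by 0.43. Complement and acute phase genes had a median of -0.24 over 12 members (camera adjusted p = 0.202; -0.16 with the station as a block and within station 1). Orm1 was called lower, and 1 higher and 2 lower passed when adjusted over the list alone. Serping1 differed by 0.79, C1qb by -0.80 and C1ra by 0.52. Cell cycle genes had a median of -0.04 over 23 members (camera adjusted p = 0.366; -0.08 with the station as a block and within station 1), with Mcm5 at -0.60, Cdkn1c at -0.45, Ccnd1 at 0.48 and Cdkn1a at -0.52. None was called over all genes or over the list alone, and 3 had an unadjusted p under 0.05 in limma.

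Of the tests that follow, those of fat, brown fat, muscle, fluidics stations, time of day, handling and probe variants were chosen after the result was seen, and those of the splits and of neighbouring genes before. The rank test for brown fat replaced a correlation of mitochondrial genes with the brown fat markers within strains, which had gone with that explanation but rested on too few arrays. A test of immediate-early genes without the muscle-bearing arrays, which had gone against muscle as their source, was dropped after it was run because each strain had 1 such array. After their results were seen, the error of the muscle test was changed from one over genes to one over arrays, and the fat and station tests were given conditions that leave them undecided.

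Brown fat and mitochondrial genes were lower in BPH together. Muscle as the whole source of the mitochondrial difference would have it vanish without the 2 arrays that carried most muscle. The oxidative phosphorylation list mean still differed there by -0.361 (SE 0.094 over 2 arrays per strain), which goes against that for the arrays left. Each strain had 1 such array, so leaving them out removed little muscle difference between the strains. With 2 arrays per strain the test cannot settle the question. The trace of muscle left in that fit was on BPH 2, in the strain with the lower values. Less fat of any kind around the BPH glands stays open: the difference of the brown fat markers lay below that of the general fat markers (-1.741, SE 0.338), but these sets were split after the values were seen, 12 of 14 fat genes were negative, and 4 of them, the called Orm1 included, are in neither set. A larger share of brown fat in the BPL samples could account for both groups: 71.9% of 64 oxidative phosphorylation genes ranked the BPL arrays as the brown fat markers did (BPL 2 above BPL 1 above BPL 3), against 17.8% of all genes. Without the muscle-bearing arrays the share that followed the markers was 48.4% against 24.8%, under the 2 times set as the bound, so this stays undecided. The question reaches beyond these groups. Among the 50 called genes lower in BPH that are not brown fat markers, 58% ranked the BPL arrays the same way. Of the 87 called genes higher in BPH 9.2% did. Without the muscle-bearing arrays these shares were 34% and 25.3%. No bound was set for these genes, so their source stays undecided too. Ucp1 reached 98186 on BPL 2 and 33362 on BPL 3, adrenal cells use the mitochondrial genes too, and a strain difference in the gland or in how brown its fat is stays open and untested.

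Immediate-early genes were higher in BPH. A difference between fluidics stations stays open: the 13 called genes had a median log2 difference of 1.333 within station 1 and 1.127 over all arrays, but station 1 holds only 1 BPH array, which was among those that called them. A different time of day at dissection may contribute: of 11 clock genes outside the immediate-early list 0 passed over the list alone in limma, but the largest difference, -0.394 for Nr1d1 (SE 0.195), leaves room for one. Handling before the glands were taken could induce these genes within minutes to hours, and 0 lines of the labels and array run files record it. A strain difference in adrenal stimulation stays open and untested.

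Several large differences rested on 1 probe set. For 40 genes with a called probe set and other tested ones, the 46 others had a median 0.449 of the called log2 difference, 37 had the same sign and 16 had less than 0.25 of it. Taking the probe set with the smallest p as the reference pulls this ratio below 1. Sequence variants between the strains under the probes could produce such a split, as could probe sets for different transcript ends or low signal, which were not tested, and with a median ratio between the bounds set this stays undecided. A strain difference in transcript structure stays open and untested.

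Neighbouring genes were compared for linked haplotypes. Leaving out pairs whose symbols start alike, both genes were called in 4 neighbouring pairs of tested genes, against 3.28 expected from 10000 random draws (permutation p = 0.415). Linked haplotypes stay open: the bound set beforehand took a count inside the random range as evidence against them, but that range reaches 6, so it leaves room for linked pairs. The 4 pairs were Rgs2 with Ivns1abp, Tmco1 with Aldh9a1, Aldh9a1 with Mgst3, and Aldh1a7 with Zfand5, of which Ivns1abp, Tmco1 and Zfand5 were chosen after their values were seen.

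The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many as 184 probe sets or 138 genes, and the highest other count was 0 for both. In limma at an unadjusted p under 0.05 the real split gave 1080 genes and 1411 probe sets, and the others 83 to 271 genes and 111 to 371 probe sets. For lists, 5 of the 10 splits gave at least the real count of 6, and the highest other was 10. The splits that put both muscle-bearing arrays on one side gave 4 lists with BPH 2, 10 with BPH 3, 7 with BPL 1 and 4 with BPL 3. Those that keep the station 2 arrays together gave 4 lists with BPL 1, 4 with BPL 2 and 6 with BPL 3, and the real comparison with the station as a block gave 9. The split of BPH 1, BPH 3 and BPL 3 against the rest also gave 9.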
